A study of Mus musculus with 24 samples.

How the data were processed

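B cell receptor sequencing was analysed for 24 libraries of B cells from dura mater, the tough outer membrane around the brain, and spleen of female C57BL/6J mice, a common inbred strain. Per the labels' protocols, infected mice received about 2000 Trypanosoma brucei parasites, the agent of African trypanosomiasis, into the peritoneal cavity and were followed to day 25. The 4 groups of 6 libraries (naive dura, infected dura, naive spleen, infected spleen) and the replicate numbers come from the sample titles. The treatment label reads naive for all 24 libraries, including the 12 whose titles say infected, and the titles were followed. The labels do not say whether the 6 libraries of a group came from separate mice, nor whether a number marks a mouse, so each p-value measures only the spread between libraries, which may be technical.

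Per the labels' protocols, RNA of isolated lymphocytes was reverse transcribed and the variable regions were amplified from primers in the constant regions by a service laboratory. The mouse genome build GRCm39 is named per the submitters' processing notes. The clone caller, the clustering of sequences, the use of molecular identifiers and the rule for listing a clone are not given in the sources used here. The reference annotation used here is of another build, so gene names were checked against it and no coordinates are given. Of 190 V gene names in the table, 174 matched a reference symbol.

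The authors deposited a table of 5482 listed clones in 72 lists, which are the heavy, kappa and lambda chains of each library. A clone is a nucleotide sequence of the CDR3, the loop formed where the V, D and J gene segments join. Per the file headers each clone has a count, a fraction, V, D and J gene names and an amino acid CDR3. The count is a whole number of reads, and the fraction deposited by the authors equals the count divided by the sum of the listed counts of that list, within 4.99e-05. There were 2013 heavy, 2840 kappa and 629 lambda entries, with 1122, 339 and 161 distinct amino acid CDR3s. No entry held a stop or a frameshift, and 0 CDR3s looked like a T cell receptor beta chain (starting CAS and ending F). The table names no isotype, so isotypes were not analysed here. It has 1 further column of values with no name, which was not used.

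Most of the lists are truncated. In 72 of 72 lists the listed reads came to at most 1000 times the lowest listed count, with a highest ratio of 0.983. A count of 1 appeared in 8 lists, none of more than 983 reads, while 0 of the 63 lists with over 1000 reads held a count of 1. A minimum near 0.1% of a larger library total would give this pattern, but neither the minimum nor that total is stated. The sum of the listed reads is therefore not the depth, and a CDR3 that is not listed may be present below the minimum. The largest library total that a minimum of 0.1% allows, 1000 times the lowest listed count, is called the ceiling total here and was used in an alternative. With that minimum, a library of up to 1000 reads would have no unlisted clone. The naive spleen lambda lists had a lowest count of 1 and 20 to 239 reads, so their ceiling total of 1000 reads is too high. Reads of amplified libraries are not independent molecules, so no counting interval is attached to single shares.

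Diversity was measured on nucleotide clones. The number of distinct clones is the expected number after rarefaction to the listed reads of the smallest list of the chain, which equalizes listed reads and not depth. For kappa chains rarefaction left each value at the number of listed clones. Clonality is 1 minus Pielou's evenness, 0 for equal shares and 1 for a single clone. The share of the 10 most abundant clones is in percent of listed reads. For abundance tests and overlap, counts of clones with the same amino acid CDR3 were summed within a library and chain. CDR3 length without the anchoring residues, net charge (lysine and arginine minus aspartate and glutamate), Kyte-Doolittle hydropathy and the share with a cysteine between the anchors were averaged with read weights. V and J usage is in percent of listed reads. Usage and CDR3 features were not computed over ceiling totals, so they describe listed clones and not whole libraries. Overlap of pairs of libraries was measured with the Morisita-Horn index, which runs from 0 to 1.

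Groups of 6 and 6 libraries were compared by exact two-sided permutation tests of the difference of means over all 924 relabelings, whose smallest p is 0.0021645. The difference between the infection effects in dura and spleen was tested with 100000 permutations of the infection labels within each tissue. Adjustment was by Benjamini-Hochberg within a family, at a threshold of 0.05. CDR3 abundance was tested on counts with edgeR's quasi-likelihood test, with the listed total of the chain as offset and no further scaling, on CDR3s with at least 10 reads in at least 3 libraries, a separate fit for each comparison and Benjamini-Hochberg adjusted p. Pairs of libraries within a group were checked for duplicates with chi-square tests of their counts. All heavy and kappa pairs differed by more than the error of counting reads, with a highest p of 2.79e-83, which does not exclude repeat libraries of the same RNA. The naive spleen lambda lists hold few reads, and the test did not tell their most similar pair apart. No batch is given in the labels.

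The comparisons, tests, alternatives and the rule for named CDR3s were fixed before the data were examined. Named CDR3s are the detected members of a fixed list of 5 public heavy chain CDR3s of B-1a cells, which are innate-like B cells, and of antibodies to phosphorylcholine. Named too are, in each abundance test, the 10 higher and 10 lower CDR3s with the largest fitted change among those with an adjusted p below 0.05 that are listed in at least 4 libraries of the higher group. The 3 CDR3s with the highest mean share in each group and up to 5 found in the most libraries complete the rule, both taken per chain. V and J classes are named if their mean share is over 5% in any group or a comparison passes. The fitted fold of a CDR3 with no listed read in a group has no meaning, so a lower bound is given instead, its mean share over ceiling totals in the higher group divided by the mean lowest listed share, over listed reads, of the other group. If the lists stop at 0.1% of reads, this is the lowest fold that the range of possible totals allows. A lower minimum would allow lower folds, so each bound given below holds on that condition. A value under 1 leaves the direction open.

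The values were also computed with minimum counts of 2 and 10, other rarefactions, the Gini coefficient, the top 1 and 100 clones, the Jaccard index, TMM and TMMwsp scaling, DESeq2 with poscounts size factors, other filters, unweighted features, shares of distinct clones, 1 substitution from the fixed list, each library left out in turn, and the replicate number as a block. After seeing the data, the ceiling total, unlisted CDR3s at the lowest listed count, nucleotide CDR3s in the abundance tests, diversity and distinct shares on amino acid CDR3s, leaving out 2 shallow lists, and libraries 1 to 3 alone were added. Unlisted CDR3s at the lowest listed count, with listed and with ceiling totals, are 2 treatments of truncation, and calls that hold in the same direction under both are counted separately. Listed totals in 1 group with ceiling totals in the other were not run in edgeR.

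The edgeR step was tested on simulated counts with known changes. It recovered 83.9% of 31 4-fold changes and 100% of 39 16-fold changes among 283 CDR3s simulated on infected against naive dura, with 1 false call in 213 unchanged. For infected against naive spleen it recovered 92.9% and 100% among 199, for naive dura against spleen 87.1% and 100% among 270, and for infected dura against spleen 92.9% and 100% among 226. These simulations had independent libraries, 1 common dispersion and no list minimum. In the data, 147 of the 188 calls between infected and naive dura had the lower group unlisted. The recovery and false calls therefore do not carry over to such calls. The permutation step recovered 99.5% of 200 differences of 4 SD among 1000 simulated, with 6 false calls. The test of the difference of infection effects recovered 100% of 100 differences of 5 SD among 300, with 10 false calls before adjustment. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.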

Results

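B cell receptor chains were read from dura mater and spleen of naive mice and of mice infected with Trypanosoma brucei for 25 days, with 6 libraries in each of 4 groups. The comparisons address how chronic infection alters the B cell repertoire of the dura and whether that repertoire differs from the one in spleen. Heavy chain lists held 37959 to 148457 reads in naive dura, 9281 to 27330 in infected dura and 69277 to 133713 in infected spleen. In naive spleen, libraries 1 to 4 held 19652 to 171736 heavy chain reads in 5 to 7 clones, and libraries 5 and 6 only 951 and 1007 reads in 577 and 59 clones. Kappa lists held 90971 to 188231 reads, and lambda lists 981 to 7297 except in naive spleen, where they held 20 to 239. These are reads in listed clones, not library depths. The mean lowest listed share of heavy reads was 1.52% in infected dura against 0.228% in naive dura and 0.168% in infected spleen, so absence from a list excludes less in infected dura. Shares below are in percent of listed reads of the chain, as mean ± SD over libraries.

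Many pairs of libraries of a group had nucleotide clones in common. On average 90.6% of heavy chain reads in naive dura were in clones listed in at least 2 of the 6 libraries (84.5% to 94.9%), 78.6% in infected dura (25.4% to 100%), 66.7% in naive spleen (23.0% to 99.8%) and 92.4% in infected spleen (86.3% to 98.2%). Some pairs shared 0 clones, such as infected dura libraries 1 and 3 and infected spleen library 3 with libraries 5 and 6. Infected spleen libraries 1 and 2 shared 89 heavy clones and libraries 5 and 6 shared 58, and kappa overlap reached 0.989 in infected and 0.990 in naive spleen. Heavy chain shares of dura libraries 4 to 6 were close to weighted sums of those of libraries 1 to 3, with a mean R2 of 0.911 in naive and 0.962 in infected dura. The libraries of a group were thus not shown to be independent in either tissue. The p-values below measure the spread between libraries only, and n counts libraries. If libraries 4 to 6 of a dura group hold material of libraries 1 to 3, the dura p-values are too small. Exact tests of 3 against 3 libraries cannot pass.

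Infected dura and naive dura had no heavy chain nucleotide clone in common in any of 36 pairs of libraries. Naive dura likewise shared none with infected spleen, in 36 pairs. Naive and infected mice are different animals, so differences between mice or pools cannot be told apart from an effect of infection here. The mean lowest listed share of 1.52% in infected dura may also hide rarer shared clones. The most abundant CDR3 in infected dura was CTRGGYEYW, joined from IGHV1-15 and IGHJ2. It held 28.1% ± 20.8 of heavy chain reads (n = 6), was listed in libraries 2 to 6 and in no naive dura library, and was at least 8.70-fold higher (edgeR adjusted p = 0.00521). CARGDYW (IGHV1-26) held 11% ± 12.8 and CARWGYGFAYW (IGHV1-76) 5.25% ± 4.10, at least 3.57-fold and 1.65-fold higher (edgeR adjusted p = 0.00674 and 0.0134). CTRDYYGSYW, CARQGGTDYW and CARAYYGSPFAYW, at 2.11%, 2.01% and 1.77%, were likewise listed in 4 infected dura libraries and in no naive one, but the range of possible totals allows folds of 0.645, 0.639 and 0.540, so their direction was left open. In the other direction, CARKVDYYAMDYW (IGHV1-78) held 7.81% ± 6.18 of naive dura reads, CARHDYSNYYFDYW (IGHV1-62-2) 5.32% ± 3.03 and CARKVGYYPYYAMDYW (IGHV2-2) 4.11% ± 3.17. None of these was listed in infected dura, where they were at least 2.13-fold, 1.65-fold and 1.3-fold lower (edgeR adjusted p = 0.00822, 3.81e-05 and 0.000102).

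Among listed clones, V and J gene usage also differed between infected and naive dura. Listed heavy reads were on average 7.23% of the ceiling total in infected dura and 44.5% in naive dura. Usage was not computed over ceiling totals, so the direction of the heavy chain changes below was left open for the whole repertoire. IGHV1-15 rose from 0.993% ± 1.16 in naive to 37.1% ± 20 in infected dura, with each infected library above each naive one (exact permutation test, adjusted p = 0.0113, n = 6 and 6). IGHV8-12 rose from 1.38% ± 1.02 to 5.74% ± 2.64 and IGHJ2 from 36.3% ± 5.76 to 66.1% ± 12.9 (exact permutation tests, adjusted p = 0.0194 for both). The IGHV1 family as a whole rose from 60% ± 6.31 to 79.8% ± 13.0 (exact test, adjusted p = 0.0489), a call that ended when any 1 of 10 of the 12 libraries was left out. IGHV1-62-2 fell from 8.03% ± 3.05 to 0.519% ± 0.909, IGHV2-2 from 8.61% ± 2.21 to 1.10% ± 1.78, IGHV1-80 from 7.64% ± 4.77 to 0.876% ± 0.973 and IGHJ1 from 19.4% ± 2.96 to 5.13% ± 3.13 (exact tests, adjusted p = 0.0113 for each). IGHV1-78 fell from 7.96% ± 5.96 to 1.18% ± 1.36 of reads (exact test, adjusted p = 0.0489), a call that also ended on leaving out any 1 of 10 libraries, while its share of distinct clones differed in the other direction, by 1.92 percentage points. Counted over distinct clones in place of reads, the IGHV1 and IGHV2-2 calls ended. IGHV1-26 was at 1.96% ± 1.03 and 16.2% ± 15.8 and did not pass (exact test, adjusted p = 0.0579), nor did IGHV1-66 at 7.68% ± 8.49 and 0.263% ± 0.644 (adjusted exact p = 0.108). Infected dura library 3 stood apart from the other 5, with IGHJ2 at 40.8% against 66.4% to 76.3%.

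Among kappa chains the IGKV6 family rose from 18.2% ± 2.95 in naive to 37.9% ± 2.57 in infected dura, with no overlap between libraries (exact permutation test, adjusted p = 0.0113, n = 6 and 6). Its genes IGKV6-15 (8.09% ± 1.78 to 15.8% ± 1.73), IGKV6-23 (3.31% ± 0.813 to 11.8% ± 1.22) and IGKV6-32 (1.54% ± 0.318 to 5.33% ± 0.294) each rose with the same adjusted exact p of 0.0113. IGKV6-15 made up a smaller share of distinct clones in infected dura, by -1.04 percentage points. The IGKV17 family rose from 2.49% ± 0.373 to 7.10% ± 0.930 and IGKV16-104 from 1.36% ± 0.227 to 2.08% ± 0.304, though the latter differed by -0.0782 points as a share of distinct clones. IGKV5-39 fell from 13.5% ± 8.20 to 0.672% ± 0.158, IGKV12-46 from 7.87% ± 2.91 to 2.94% ± 0.820, IGKV14 from 5.84% ± 0.953 to 2.04% ± 0.476 and IGKV1 from 4.81% ± 0.646 to 2.66% ± 0.358 (exact tests, adjusted p = 0.0113 for each). Among lambda chains IGLV1 rose from 60.9% ± 2.93 to 72.2% ± 4.47 and IGLV3 from 6.66% ± 1.58 to 12.1% ± 2.43, while IGLV2 fell from 32.5% ± 3.14 to 15.6% ± 2.59 (exact tests, adjusted p = 0.0194, 0.0113 and 0.0113). As shares of distinct clones the IGKV14, IGLV1 and IGLV2 calls ended. In all, 33 V and J classes passed for infected against naive dura among 345 tests over 5 comparisons. Fewer classes passed as shares of distinct amino acid CDR3s, with the count given among the processing alternatives below. The IGKV16 family held IGKV16-104 alone, so 1 measure counts as 2 classes here and in each later count.

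The kappa CDR3s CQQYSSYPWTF and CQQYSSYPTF (both IGKV6-23), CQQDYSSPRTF (IGKV6-32) and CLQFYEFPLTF (IGKV14-130) were listed in infected dura at 0.753% ± 0.342, 0.753% ± 0.565, 0.529% ± 0.0730 and 0.512% ± 0.0878 and in no naive dura library. The first 2 were at least 1.26-fold higher each, and the direction of the other 2 was left open, with lowest folds of 0.874 and 0.846 (edgeR adjusted p = 1.23e-05, 0.00674, 9.05e-06 and 9.80e-06). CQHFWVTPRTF (IGKV12-46) and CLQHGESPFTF (IGKV14-126) held 3.53% ± 3.09 and 1.35% ± 0.357 in naive dura and were at least 5.88-fold and 2.24-fold lower in infected dura (edgeR adjusted p = 0.00674 and 7.78e-06). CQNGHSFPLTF (IGKV5-39) held 10.7% ± 6.73 of naive and 0.242% ± 0.124 of infected dura reads. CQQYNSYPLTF (IGKV6-15) held 3.75% ± 1.05 and 8.05% ± 1.05, and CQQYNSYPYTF of the same V gene 2.8% ± 0.565 and 4.96% ± 0.718. The lambda CDR3 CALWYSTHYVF (IGLV2) was at 24% ± 1.88 in naive and 12.4% ± 2.34 in infected dura, and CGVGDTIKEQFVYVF (IGLV3) at 6.41% ± 1.5 and 11.8% ± 2.18.

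In total, edgeR called 188 of 283 CDR3s between infected and naive dura, 56 higher and 132 lower in infected dura, and 97 of the 132 were heavy chain CDR3s. This split rests on how unlisted CDR3s are counted. With unlisted CDR3s at the lowest listed count, 121 were higher and 52 lower, and with ceiling totals 68 and 117. It was 32 and 28 with 10 reads in 6 libraries as the filter, 18 and 13 with the replicate number as a block and 15 and 14 in libraries 1 to 3. Calls that held in both were 76, with 12 of 111 heavy, 56 of 69 kappa and 8 of 8 lambda CDR3s. All 6 CDR3s named above as listed in the infected heavy chain alone were among them, as were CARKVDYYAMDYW, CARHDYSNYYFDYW and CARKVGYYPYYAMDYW. The calls for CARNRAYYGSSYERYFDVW, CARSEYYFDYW, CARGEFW, CARGAYW and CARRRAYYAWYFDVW, at 3.19%, 2.90%, 2.89%, 2.09% and 1.8% of naive dura reads, did not hold. With libraries 1 to 3 alone edgeR called 29, and without any of the 6 infected dura libraries in turn between 90 and 107.

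Infected dura listed fewer heavy chain clones than naive dura. At equal listed reads there were 26.8 ± 9.37 distinct heavy clones against 108 ± 17.1 (exact permutation test, adjusted p = 0.0139, n = 6 and 6), whereas kappa clones numbered 137 ± 3.66 and 133 ± 6.86 (adjusted exact p = 0.283). As amino acid CDR3s these were 26.0 ± 9.53 and 105 ± 17.1 in the heavy chain and 120 ± 2.68 and 122 ± 6.62 in kappa (adjusted exact p = 0.0122 and 0.713). The lowest listed share was 0.857% to 1.94% of heavy reads in infected and 0.187% to 0.254% in naive dura libraries, and rarefaction does not remove this limit on the length of a list. A smaller number of heavy clones in the infected tissue therefore does not follow. The 10 most abundant heavy clones held 70.2% ± 16.2 of listed reads in infected and 43.3% ± 4.21 in naive dura (adjusted exact p = 0.0300), a call that ended without naive dura library 4, 5 or 6. Over ceiling totals this difference had the opposite sign, 5.01% ± 1.95 against 19.3% ± 3.72 (adjusted exact p = 0.00749), so the direction was not determined. Clonality of the heavy chain was 0.179 ± 0.0996 and 0.127 ± 0.0150 and did not pass (adjusted exact p = 0.255).

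**Figure D1:**
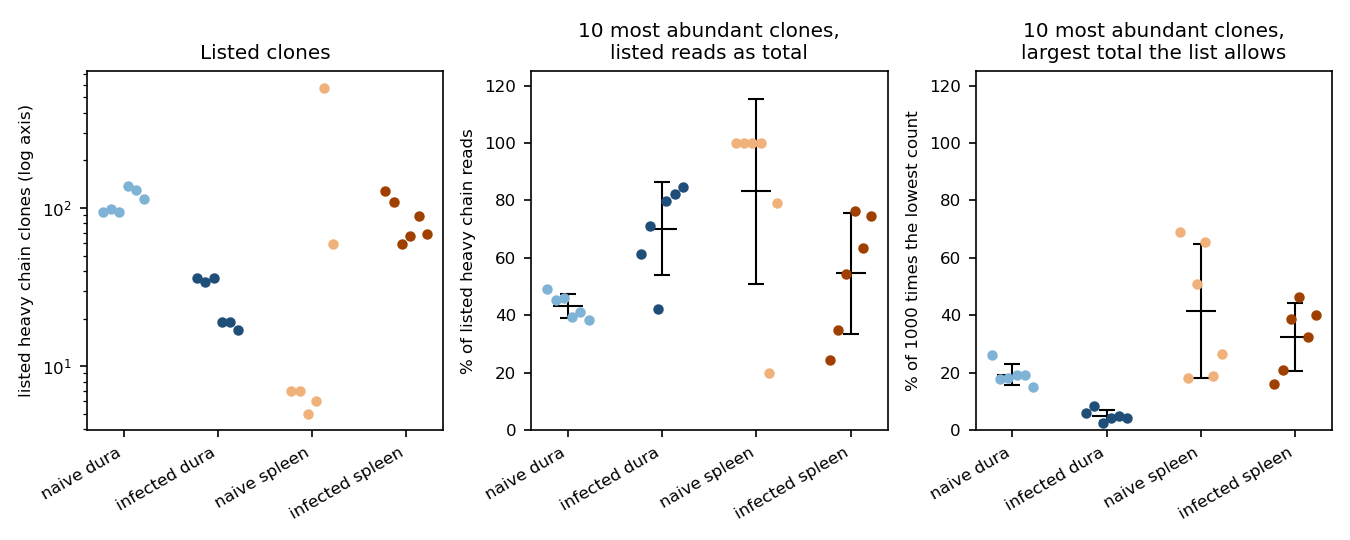
Heavy chain lists of the 24 libraries, 1 point per library (left panel, number of listed clones on a log axis; middle and right panels, share in percent of the 10 most abundant clones over listed reads and over the ceiling total of 1000 times the lowest count). Horizontal bars and whiskers are mean and SD, and the infected dura mean is above the naive one over listed reads (70.2% against 43.3%) and below it over ceiling totals (5.01% against 19.3%).

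Listed CDR3s of infected dura were also shorter and more hydrophilic in the heavy chain. These means cover listed clones alone, and the lowest listed share was higher in infected than in naive dura, so they may not hold for all CDR3s. Mean length was 8.23 ± 0.994 residues in infected and 11.6 ± 0.197 in naive dura (exact test, adjusted p = 0.0162), and mean hydropathy -1.22 ± 0.231 and -0.805 ± 0.0191 (adjusted exact p = 0.0451). Infected dura library 3, in which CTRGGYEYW held 7.21% of reads, stood apart at 10.1 residues and -0.765. Kappa hydropathy fell from -1.16 ± 0.0118 to -1.27 ± 0.0179 (adjusted exact p = 0.0162), a difference that did not pass without read weights. Kappa net charge was -0.188 ± 0.0150 in infected and -0.138 ± 0.0360 in naive dura (adjusted exact p = 0.0278), and without read weights the difference was 0.00810, of the other sign. Lambda length rose from 9.28 ± 0.0649 to 9.48 ± 0.108 and lambda net charge fell from -0.0585 ± 0.0166 to -0.110 ± 0.0256 (adjusted exact p = 0.0162 for both), and both changed sign without read weights, as did lambda hydropathy. CDR3s with a cysteine between the anchors did not differ detectably in any chain or comparison with all libraries (lowest adjusted exact p = 0.314). Without naive spleen library 5 the heavy difference between infected and naive spleen passed, at 0.765 in place of 0.379 percentage points.

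In spleen, infection went with changes in kappa and heavy chain genes. The IGKV6 family rose from 13.6% ± 6.55 in naive to 31% ± 4.90 in infected spleen, IGKV6-32 from 1.57% ± 1.54 to 6.70% ± 1.58 and IGKV16-104 from 0.303% ± 0.363 to 6.36% ± 2.55, each without overlap of libraries (exact permutation tests, adjusted p = 0.0113, n = 6 and 6). IGKV6-23 rose from 1.95% ± 2.11 to 8.05% ± 3.49 and IGKV2 from 0.507% ± 0.754 to 3.75% ± 2.86 (adjusted exact p = 0.0336 and 0.0467), calls that ended when any 1 of 5 and of 8 of the 12 libraries was left out. IGKV10-94 fell from 10.1% ± 7.41 to 2.09% ± 0.438 and IGKV12-44 from 9.16% ± 7.52 to 1.92% ± 1.17 (adjusted exact p = 0.0401 and 0.0489), calls that ended likewise for any 1 of 6 and of 9 libraries. As shares of distinct clones the IGKV6-23, IGKV2 and IGKV10-94 calls ended, as did those of IGHV1-26 and IGHJ2 below. In the heavy chain, IGHV1-76 rose from 0.593% ± 0.939 to 4.56% ± 2.76 (adjusted exact p = 0.0113), IGHV1-26 from 0.891% ± 1.43 to 5.10% ± 3.39 (0.0489 by the same exact test) and IGHJ2 from 12.9% ± 14.1 to 42.3% ± 8.56 (adjusted exact p = 0.0273), and the IGHV1 family fell from 83.9% ± 13.6 to 50% ± 18.0 (adjusted exact p = 0.0273). The IGHV1-26 call ended when any 1 of 10 libraries was left out and the IGHV1 call for any 1 of 3. Naive spleen libraries 1 to 4 listed neither IGHV1-76 nor IGHV1-26, so both naive means rest on the 2 shallow lists. Without these lists IGHV1-76 passed (adjusted exact p = 0.0193) and IGHV1-26 did not (0.0538 by the same exact test). Libraries 1 to 4 list only 5 to 7 heavy clones each, so the IGHV1-76 pass is no added support for an effect of infection. IGHV8-5 was at 23.8% ± 29.0 in infected and 2.69% ± 4.17 in naive spleen and did not pass (adjusted exact p = 0.307). It carried the most abundant heavy CDR3s of infected spleen, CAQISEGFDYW at 13.0% ± 16.5 and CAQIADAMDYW at 7.58% ± 9.48, each listed in 3 of the 6 libraries, as was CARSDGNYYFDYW (IGHV1-7) at 3.77% ± 5.96.

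CARGTYW (IGHV1-80, IGHJ3) took 38.7% ± 38.7 of heavy reads and was listed in 4 naive spleen libraries and no other group. It was at least 111-fold lower in infected spleen (edgeR adjusted p = 0.0245). Naive spleen libraries 1 to 4 listed 5 to 7 heavy clones, so this fold and that against naive dura rest on short lists. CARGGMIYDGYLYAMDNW (IGHV1-55) reached a mean of 10.4% ± 25.6 from 1 library and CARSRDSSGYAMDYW (IGHV1-81) 9.66% ± 18.1 from 3. Kappa CDR3s absent from naive spleen lists included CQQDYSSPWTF (IGKV6-32) at 1.81% ± 1.41 of infected spleen reads, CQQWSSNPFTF (IGKV4-59) at 1.60% ± 1.30 and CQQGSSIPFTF (IGKV4-91) at 0.823% ± 0.359, at least 5.77-fold, 5.47-fold and 2.77-fold higher (edgeR adjusted p = 0.0192, 0.0138 and 0.0138). The other 7 named as higher were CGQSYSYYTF, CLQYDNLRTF, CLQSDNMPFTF, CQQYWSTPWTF, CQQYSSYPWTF, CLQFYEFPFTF and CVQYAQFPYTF, at 0.806%, 0.703%, 0.693%, 0.623%, 0.532%, 0.417% and 0.379%. Listed in naive and not in infected spleen were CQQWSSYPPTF (IGKV4-55) at 3.62% ± 3.71, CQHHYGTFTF and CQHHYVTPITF (both IGKV12-44) at 2.05% ± 1.94 and 1.63% ± 2.11, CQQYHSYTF (IGKV6-15) at 1.55% ± 1.79 and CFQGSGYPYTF (IGKV4-63) at 0.981% ± 1.23. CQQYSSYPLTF (IGKV6-23) was the most abundant kappa CDR3 of infected spleen at 8.77% ± 2.10, against 0.257% ± 0.361 in naive spleen.

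Between infected and naive spleen edgeR called 56 of 199 CDR3s, 36 higher and 20 lower, of which 52 were kappa and 4 heavy. With detection in 2 libraries as the filter the split turned, to 19 higher and 28 lower. It was 6 and 0 with 10 reads in 6 libraries as the filter. Unlisted CDR3s at the lowest listed count gave 64 higher and 26 lower, and with ceiling totals 68 and 27. In both treatments of unlisted CDR3s 42 held, 4 heavy and 38 kappa. Without naive spleen library 2 or 3 the count was 37 or 32. Kappa clones at equal listed reads rose from 70 ± 27.1 in naive to 134 ± 7.53 in infected spleen, and the share of the 10 most abundant fell from 58.4% ± 15.4 to 30.8% ± 3.65 (exact tests, adjusted p = 0.0139 for both). As amino acid CDR3s they rose from 66 ± 23.3 to 117 ± 6.27 (adjusted exact p = 0.0122). Rarefaction left these kappa numbers at those of the listed clones. They count clones above a minimum that is not stated and not all clones of a library. Kappa clonality fell from 0.194 ± 0.121 to 0.0829 ± 0.0112 (adjusted exact p = 0.0300), by 0.111, with naive spleen library 6 at 0.430 and a difference of -0.0640 without it. Heavy chain clones numbered 83.0 ± 26.2 in infected spleen and 110.0 ± 229.8 in naive spleen, a mean set by the 577 of library 5. Without the 2 shallow lists the difference was 77.0 higher in infected spleen (adjusted exact p = 0.0143), opposite in sign. Kappa net charge fell from 0.0546 ± 0.0878 to -0.200 ± 0.0481 (adjusted exact p = 0.0162), which had the other sign without read weights, and kappa length rose from 8.76 ± 0.110 to 8.90 ± 0.0186 residues (adjusted exact p = 0.0451). The length call ended when any 1 of 11 of the 12 libraries was left out, and without read weights the difference was 0.0312 and did not pass. The V and J classes that passed were 12, and 22 without naive spleen library 5.

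**Figure D2:**
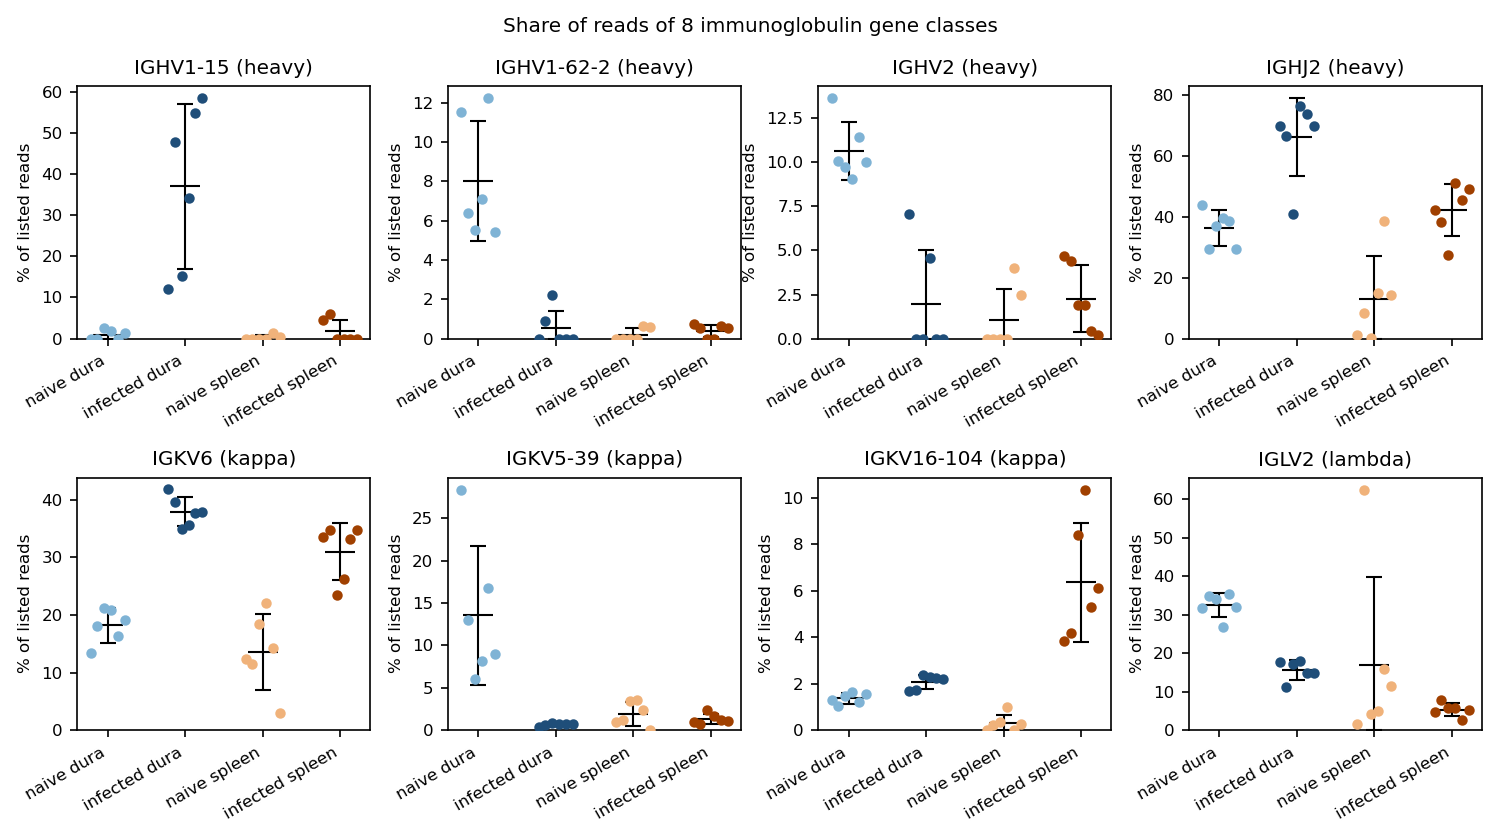
Share of listed reads in percent for 8 gene classes, 1 point per library in 4 groups of 6, with horizontal bars and whiskers for mean and SD (whiskers end at 0 where the SD exceeds the mean). IGHV1-15 is high in infected dura (37.1%), IGKV6 is high in both infected tissues (37.9% and 31%), and IGKV5-39 is high in naive dura (13.5%).

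The infection effect differed between the tissues for 17 V and J classes (permutation tests of the difference, n = 6 per group). The IGHV1-15 increase was larger in dura by 34.6 percentage points (adjusted permutation p = 0.0122). The change of IGKV5-39 was -12.9 points in dura and -0.569 in spleen, and that of IGKV16-104 was 0.721 in dura and 6.06 in spleen (adjusted permutation p = 0.0113 and 0.0152). For the IGHV1 family, IGHV2-2 and IGHJ1 the changes were 19.8, -7.51 and -14.3 points in dura and -33.9, 0.569 and 5.64 in spleen (adjusted permutation p = 0.0113 for each difference). The spleen changes of IGHV2-2 and IGHJ1 did not pass by themselves (adjusted exact p = 0.6253 and 0.115). Naive spleen libraries 1 to 4 listed neither IGHV2-2 nor IGHJ1, perhaps as they list 5 to 7 heavy clones. The direction of the heavy changes in dura was left open above for the whole repertoire. The heavy chain differences between tissues therefore describe listed clones and do not establish an effect of infection particular to a tissue. For the IGKV6 family the effects of 37.9% against 18.2% in dura and 31% against 13.6% in spleen were not shown to differ (adjusted permutation p = 0.951).

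Naive dura differed from naive spleen in heavy and kappa genes. IGHV1-62-2 was at 8.03% ± 3.05 in dura and 0.204% ± 0.317 in spleen, IGHV2-2 at 8.61% ± 2.21 and 0.507% ± 0.819, IGHV8-8 at 5.22% ± 0.943 and 0.604% ± 1.07 and IGHJ1 at 19.4% ± 2.96 and 3.13% ± 5.26 (exact permutation tests, adjusted p = 0.0113, n = 6 and 6). Naive spleen libraries 1 to 4 listed none of these 4, and all 4 passed without the 2 shallow lists (adjusted exact p = 0.0193 for each). Lists of 5 to 7 heavy clones leave most classes at 0, so this is no added support for a difference between the tissues. IGKV5-39 at 13.5% ± 8.20 against 1.91% ± 1.41 and IGKV12-46 at 7.87% ± 2.91 against 0.567% ± 0.888 were higher in dura, and the IGKV4 family at 2.55% ± 1.62 against 17.1% ± 10.3 and the IGKV10 family at 4.21% ± 0.602 against 18.9% ± 19.0 were lower (adjusted exact p = 0.0113 for each). The IGKV10 mean in spleen rests on library 6 at 56.4%, without which the difference was -7.14 in place of -14.7 points, and the call ended when any 1 of the 6 dura libraries was left out. The largest bound among the named higher CDR3s was that of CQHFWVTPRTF (IGKV12-46), at least 8.58-fold, followed by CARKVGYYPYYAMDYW (IGHV2-2), at least 8.20-fold (edgeR adjusted p = 0.0135 and 0.00119). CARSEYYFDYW (IGHV1-66), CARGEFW (IGHV1-80), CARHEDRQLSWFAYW (IGHV1-62-2), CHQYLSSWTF (IGKV8-27), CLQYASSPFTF (IGKV9-120), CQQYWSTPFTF (IGKV13-85) and the IGKV5-39 CDR3s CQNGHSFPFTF and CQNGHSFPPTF were also listed in dura and in no naive spleen library, at 0.673% to 2.90% of reads. CARGTYW and the kappa CDR3s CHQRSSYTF (IGKV4-70), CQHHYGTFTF, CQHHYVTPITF and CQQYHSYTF were listed in naive spleen and in no naive dura library, with bounds of 81.9-fold, 8.21-fold, 4.84-fold, 3.85-fold and 3.67-fold. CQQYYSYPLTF (IGKV8-30) was abundant in both, at 5.74% ± 4.08 and 7.36% ± 9.28.

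Between naive dura and naive spleen edgeR called 134 of 270 CDR3s, 111 higher and 23 lower in dura, of which 62 held in both treatments of unlisted CDR3s (24 heavy and 38 kappa). Without the 2 shallow lists the count was 89, and without naive spleen library 1, 2, 3, 4 or 5 it was 31, 30, 30, 40 or 58. Naive dura listed more kappa clones at equal listed reads, 133 ± 6.86 against 70 ± 27.1 (adjusted exact p = 0.0139), or 122 ± 6.62 against 66 ± 23.3 amino acid CDR3s (adjusted exact p = 0.0122). These kappa numbers are again those of the listed clones, which rarefaction did not change. Clonality in the heavy chain was lower in naive dura, 0.127 ± 0.0150 against 0.416 ± 0.202 (adjusted exact p = 0.0426). The heavy chain clonality difference did not pass with the Gini coefficient (-0.0894) or when any 1 of the naive dura libraries was left out. The 10 most abundant clones held 43.3% ± 4.21 against 83.2% ± 32.2 of heavy reads and 32.4% ± 7.38 against 58.4% ± 15.4 of kappa reads (adjusted exact p = 0.0426 and 0.0195). Lists of 5 to 7 clones set the heavy difference, with shares of 100% in naive spleen libraries 1 to 4. It did not pass over ceiling totals (-22.2 points) or when any 1 of 11 of the 12 libraries was left out. Usage passed for 21 V and J classes.

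Among listed clones, infected dura differed from infected spleen in heavy and light chain genes. IGHV1-15 was at 37.1% ± 20 in dura and 1.76% ± 2.78 in spleen and IGHV8-12 at 5.74% ± 2.64 and 0.364% ± 0.497 (exact permutation tests, adjusted p = 0.0113, n = 6 and 6). IGKV6 was higher in dura, 37.9% ± 2.57 against 31% ± 4.90, as was IGKV6-15, 15.8% ± 1.73 against 8.07% ± 1.48, although as a share of distinct clones IGKV6-15 was lower by -0.611 points. IGKV16-104 (2.08% ± 0.304 against 6.36% ± 2.55) and the IGKV4 family (3.16% ± 0.444 against 7.98% ± 2.27) were lower in dura, and IGLV2 was higher at 15.6% ± 2.59 against 5.27% ± 1.69 (adjusted exact p = 0.0113 for each). The IGKV6 and IGKV16-104 calls ended as shares of distinct clones. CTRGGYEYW and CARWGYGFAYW were listed in no infected spleen library and were at least 11.8-fold and 2.24-fold higher in dura (edgeR adjusted p = 0.0116 and 0.0313). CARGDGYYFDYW, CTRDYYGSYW and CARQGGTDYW, at 2.15%, 2.11% and 2.01% of infected dura reads, were called higher, but with lowest folds of 0.850, 0.877 and 0.870 their direction was left open, and the call for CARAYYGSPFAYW (1.77%) did not hold in both treatments of unlisted CDR3s. Kappa CDR3s listed in infected dura alone of the pair were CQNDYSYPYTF, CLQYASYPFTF, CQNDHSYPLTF and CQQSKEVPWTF, at 0.314% to 0.413% and with lowest folds of 0.708 to 0.943. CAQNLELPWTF (IGKV2-109) at 1.40% ± 1.48 and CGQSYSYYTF (IGKV6-20) at 0.806% ± 0.964 of infected spleen reads were at least 3.28-fold and 1.91-fold lower in dura (edgeR adjusted p = 0.00269 and 0.0418), as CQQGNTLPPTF and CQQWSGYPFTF were, at least 1.28-fold and 1.15-fold.

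Between infected dura and infected spleen edgeR called 51 of 226 CDR3s, 30 higher and 21 lower in dura, and the split varied with the method. It was 94 higher and 20 lower with unlisted CDR3s at the lowest listed count, 39 and 65 with ceiling totals, 32 and 39 with TMMwsp scaling, 31 and 64 with DESeq2 and 13 and 19 in libraries 1 to 3. Calls that held in both treatments of unlisted CDR3s were 26, with 7 heavy, 16 kappa and 3 lambda. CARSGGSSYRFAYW, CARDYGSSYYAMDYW, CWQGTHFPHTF, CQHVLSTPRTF, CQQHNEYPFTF and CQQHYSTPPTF, at 0.316% to 1.44% of infected spleen reads, were called lower in dura and did not hold. Without infected dura library 2, 4, 5 or 6 the count was 9, 8, 8 or 8. Infected dura listed fewer heavy clones than infected spleen at equal listed reads, 26.8 ± 9.37 against 83.0 ± 26.2 (adjusted exact p = 0.0139), or 26.0 ± 9.53 against 82.8 ± 26.0 amino acid CDR3s (adjusted exact p = 0.0122), a count limited by the higher lowest listed share in infected dura as above, with shorter CDR3s of 8.23 ± 0.994 against 10.7 ± 0.617 residues (adjusted exact p = 0.0216). Lambda clonality was 0.305 ± 0.0174 in dura and 0.461 ± 0.103 in spleen (adjusted exact p = 0.0139), which did not pass with the Gini coefficient. Usage passed for 24 classes, and for 15 without infected dura library 5.

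Sharing of CDR3s between libraries of a group differed by chain. The mean Morisita-Horn overlap of kappa CDR3s was 0.761 in naive dura, 0.959 in infected dura, 0.278 in naive spleen and 0.779 in infected spleen. The differences between infected and naive spleen, between naive dura and spleen and between infected dura and spleen passed (permutation of libraries, exact adjusted p = 0.00649 for each, n = 6 per group), and that between infected and naive dura did not (adjusted exact p = 0.198). Heavy chain overlap within a group was 0.521 in naive dura, 0.469 in infected dura, 0.246 in naive spleen and 0.214 in infected spleen, and of the 4 comparisons naive dura against spleen passed (adjusted exact p = 0.0390), with differences of 0.153 to 0.373 when a library was left out and the call lost for any 1 of 7 of the 12. Lambda overlap was 0.977 in naive and in infected dura, 0.636 in naive spleen and 0.859 in infected spleen. Dura against spleen passed in naive and in infected mice (adjusted exact p = 0.00649 and 0.0104). The naive call was lost with the Jaccard index and without naive spleen library 2, and the infected call without infected spleen library 1 or 2. A pair of libraries shared on average 37.8 heavy nucleotide clones in naive dura, 6.20 in infected dura, 3.47 in naive spleen and 17.3 in infected spleen. Naive dura shared none with infected spleen, in 36 pairs, and infected dura shared on average 0.194 with infected spleen. Same-numbered dura and spleen libraries overlapped no more than others by these tests (lowest adjusted exact p = 0.667). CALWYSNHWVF, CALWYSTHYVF and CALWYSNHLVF, all lambda, were the 3 CDR3s listed in all 24 libraries, with 0 heavy and 0 kappa CDR3s, and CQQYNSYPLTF was among the kappa CDR3s listed in 23.

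**Figure D3:**
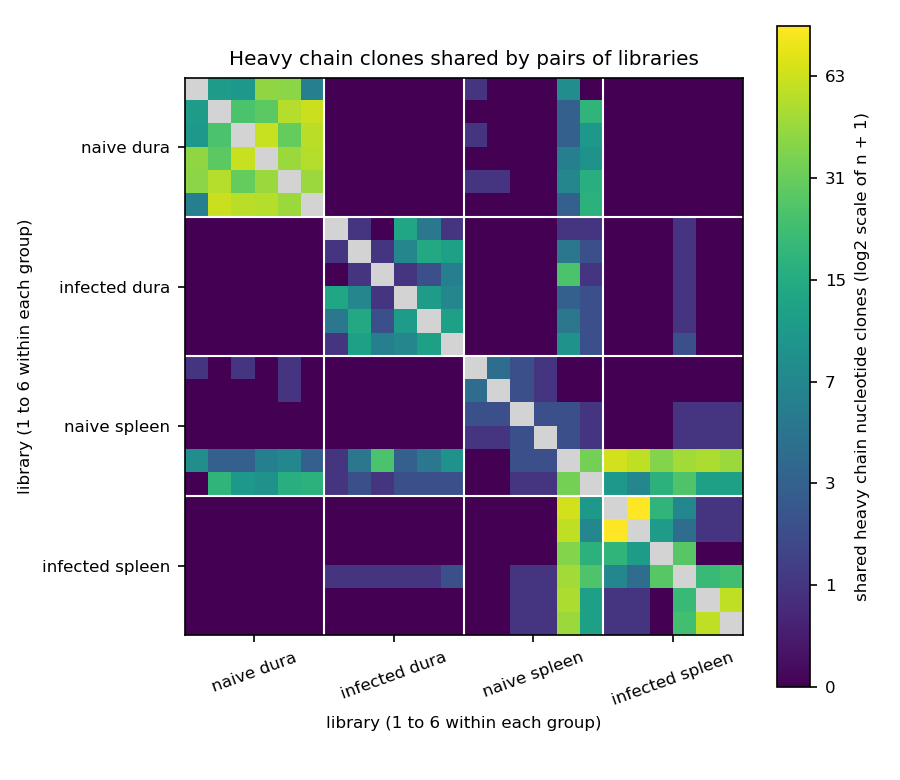
Number of heavy chain nucleotide clones shared by each pair of the 24 libraries, with libraries on both axes in 4 groups of 6, colour on a log2 scale of the number plus 1, and the diagonal in grey. Pairs of naive and infected dura libraries share 0 clones, pairs within naive dura share up to 62, and naive spleen library 5 shares clones with libraries of the other 3 groups.

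No library listed any of the 5 CDR3s of the fixed list for B-1a cells and phosphorylcholine antibodies. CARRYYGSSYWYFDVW, which differs from a list member by 1 substitution, was listed in infected spleen library 1 with 730 reads (0.833% of heavy reads) and in naive spleen library 5 with 1 read.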

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

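The tests of explanations and of other splits of the libraries in this part were chosen after the result was seen, while the comparisons of infection effects between tissues were planned.

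Pairs of naive dura libraries shared a mean of 37.8 heavy chain nucleotide clones, and pairs of infected dura libraries 6.20, while no naive dura library shared any with infected dura. Of the amino acid CDR3s shared by pairs of naive dura libraries 97.7% had the same nucleotide sequence, which argues against independent rearrangements selected for a common CDR3. Ratios of shares cannot tell reads carried over in sequencing from other sources. The list minimum lets only 9.52% of the shared clones show a share in the second library under 5% of that in the first. Material shared between libraries may explain the pattern: naive dura libraries 4 to 6 were non-negative sums of libraries 1 to 3 with a mean R2 of 0.911, rank 1 of the 20 choices of 3 source libraries (median 0.622), and in infected dura the R2 was 0.962 and again rank 1. Library 6 of naive dura, for example, had weights of 0.574 and 0.436 on libraries 2 and 3. In naive dura the heavy weights of libraries 4 to 6 summed to 0.950, 1.09 and 1.01. Sums of this size argue against carry-over of a small part of reads as the source of what these libraries share with libraries 1 to 3. Carry-over at shares under the list minimum cannot be seen. Kappa mean R2 was 0.975 in naive and 0.974 in infected dura, rank 1 in both (medians 0.803 and 0.941). In spleen libraries 1 to 3 ranked between 15 and 20, although infected spleen libraries 1 and 2 shared 89 clones and 5 and 6 shared 58. Dura libraries 4 to 6 were thus close to mixtures of libraries 1 to 3 and cannot be counted as independent of them. Whether mice were pooled or libraries repeated, in either tissue, was not tested.

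The shallow heavy chain lists of naive spleen libraries 5 and 6 held clones of other groups, including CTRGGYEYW of infected dura. Clones listed in other groups took 50.6% and 36.1% of their reads, a mean of 43.4%, against at most 1.54% in naive spleen libraries 1 to 4. In lists of only 951 and 1007 reads, a small number of reads carried over from other libraries, against the depth of those libraries, is enough for 43.4%, so that carry-over may account for these clones. Whether the same clones were present in these naive spleens cannot be told apart from that, since the 1.54% of the deeper lists sets no bound for other animals.

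The 10 most abundant heavy clones held a larger share of listed reads in infected than in naive dura. Over ceiling totals the difference was -14.3 percentage points, as it would be if the minimum for listing and the listed total as denominator set the direction. Larger clones in infected dura cannot be told apart from this, since the infected mean of 5.01% over ceiling totals is a lower bound if the lists stop at 0.1% of reads, and the true totals are not given. The listed reads were on average 7.23% of the ceiling total in infected dura and 44.5% in naive dura.

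For the counts of called CDR3s, 100 splits of the libraries were drawn for each comparison, the real one included. In each comparison 1 split, the real one, gave as many CDR3s. This does not exclude chance, since libraries of a group had clones in common and were not shown to be independent. Where libraries of a group share material, splits that mix the groups would give fewer calls whatever the source of the difference. The real counts and the highest of the other splits were 188 and 0 for infected against naive dura, 56 and 36 for infected against naive spleen, 134 and 106 for naive dura against spleen and 51 and 0 for infected dura against spleen.

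Of 319 groups of 6 libraries, 52 had a library far from the other 5 by Dixon's test, where chance flags about 1 in 20 groups, here 16, if values are normally distributed. In 10 of the 52 the other 5 libraries were all at 0, where any listed value lies far from them, so that the chance figure does not hold for such shares. Values are that library's against the range of the others, in percent of reads for genes and shares. Naive spleen library 5 stood apart in heavy number of distinct clones (577 against 4.74 to 59.0), heavy share of the 10 most abundant clones (19.8 against 79.1 to 100), kappa CDR3 net charge (-0.107 against 0.0456 to 0.132) and heavy share of CDR3s with an inner cysteine (2.31 against 0). The same library lay outside the other 5 in lambda share of CDR3s with an inner cysteine (4 against 0 to 0.418), IGHV3 (6.94 against 0 to 0.794), IGHV9 (4.31 against 0 to 1.39) and IGKV1 (10.1 against 0.169 to 2.8). That library differed from the rest of its group in IGKV13 (3.02 against 0 to 0.480), IGKV17 (4.92 against 1.02 to 2.03), IGHV1-5 (1.89 against 0 to 0.596), IGHV1-66 (0.315 against 0) and IGKV12-46 (2.37 against 0 to 0.280). Naive spleen library 6 lay outside the other 5 in kappa clonality (0.430 against 0.0816 to 0.173), kappa CDR3 length (8.98 against 8.68 to 8.76), IGKV10 (56.4 against 7.32 to 17.3) and IGKV15 (16.9 against 0 to 0.401). The same library differed from the rest of its group in IGKJ4 (57.4 against 12.2 to 14.6), IGHV1-55 (63.5 against 0 to 2.00), IGHV1-78 (2.98 against 0) and IGKV10-96 (38.2 against 0.799 to 5.16). Infected dura library 3 differed from the rest of its group in heavy CDR3 length (10.1 against 7.41 to 8.34), heavy CDR3 hydropathy (-0.765 against -1.38 to -1.23), IGHV5 (9.19 against 0) and IGHV9 (13.3 against 0 to 3.6). The same library stood apart in IGHJ2 (40.8 against 66.4 to 76.3), IGHV1-55 (3.84 against 0) and IGKV6-32 (5.91 against 5.08 to 5.31). Naive spleen library 4 stood apart in kappa share of CDR3s with an inner cysteine (0.174 against 0), IGKV16 (0.987 against 0 to 0.339), IGHV1-81 (46.0 against 0 to 8.48), IGHV8-12 (14.8 against 0 to 0.946) and IGKV16-104 (0.987 against 0 to 0.339). Naive spleen library 2 lay outside the other 5 in IGLJ1 (15.3 against 69.2 to 97.9), IGLJ2 (77.8 against 1.67 to 19.2), IGLV1 (22.2 against 80 to 97.9) and IGLV2 (62.5 against 1.67 to 16). Infected spleen library 3 differed from the rest of its group in kappa number of distinct clones (119 against 133 to 139), IGKV15 (0.268 against 0), IGHV1-81 (4.03 against 0 to 0.590) and IGHV8-8 (6.79 against 0 to 2.05). Infected dura library 2 stood apart in kappa CDR3 length (8.90, below 8.91 in the other 5). Infected dura library 1 lay outside the other 5 in kappa CDR3 hydropathy (-1.3 against -1.27 to -1.26), lambda share of CDR3s with an inner cysteine (1.19 against 0 to 0.295), IGKV13 (3.99 against 1.85 to 2.47), IGHV1-66 (1.58 against 0) and IGHV1-81 (1.8 against 0). Naive dura library 6 differed from the rest of its group in lambda share of CDR3s with an inner cysteine (0.128 against 0). Naive dura library 1 stood apart in IGKV4 (5.68 against 1.20 to 2.67) and IGKJ1 (24.8 against 28.0 to 29.7). Naive dura library 4 lay outside the other 5 in IGLJ2 (32.6 against 37.4 to 39.8) and IGLV1 (66.8 against 59.1 to 60).

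Effects of infection, infected minus naive, differed between dura and spleen by permutation of the infection labels within each tissue for 26 measures, among which the IGKV16 family and IGKV16-104 are the same values and count as 2. For diversity and CDR3 features the dura effect minus the spleen effect was past the threshold for kappa number of distinct clones (-59), heavy share of the 10 most abundant clones (55.4), kappa share of the 10 most abundant clones (24.2), heavy CDR3 length (-4.51) and kappa CDR3 length (-0.158). Further features were lambda CDR3 length (0.306), kappa CDR3 net charge (0.204), lambda CDR3 net charge (-0.107) and heavy CDR3 hydropathy (-0.610). Among genes, in percentage points, the difference passed for IGHJ1 (-19.96), IGKJ1 (-9.98), IGHV1 (53.8), IGHV2 (-9.89), IGHV3 (-5.26) and IGKV14 (-4.90). It also passed for IGKV16 (-5.34), IGKV5 (-11.1), IGHV1-15 (34.6), IGHV1-62-2 (-7.70), IGHV2-2 (-8.08) and IGHV8-12 (6.62). The last were IGKV10-94 (8.45), IGKV12-46 (-6.22), IGKV16-104 (-5.34), IGKV5-39 (-12.3) and IGLV3 (9.94). Over ceiling totals the heavy difference for the 10 most abundant clones was -5.17, of the other sign (adjusted permutation p = 0.764). Naive spleen libraries 1 to 4 list 5 to 7 heavy clones, which fixes their share at 100%, so the difference of 55.4 is no measure of clone sizes. The heavy gene and CDR3 feature differences rest on the same short lists and describe listed clones alone. With 1 of the 24 libraries left out, the call ended in 17 of 24 fits for the kappa share of the 10 most abundant clones and in 16 of 24 each for lambda CDR3 length, kappa CDR3 net charge and IGHV3. On amino acid CDR3s the kappa share difference was 22.3 and did not pass. The IGKV10-94 call ended when any 1 of 6 libraries was left out, that of heavy CDR3 length for any 1 of 5 and that of kappa CDR3 length for any 1 of 4. Without read weights the kappa net charge difference was -0.0157, of the other sign, and lambda CDR3 length (0.231), lambda net charge (-0.149) and kappa CDR3 length (-0.0524) did not pass. As a share of distinct clones the IGKV14 difference was 0.593, of the other sign, and IGHV2, IGHV3, IGKV5, IGHV1-62-2, IGHV2-2 and IGKV10-94 did not pass. The IGHV8-12 difference was 4.18 without naive spleen library 4.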

How the results depend on the processing

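The alternatives ceiling total, unlisted CDR3s at the lowest count, nucleotide CDR3s, diversity and distinct shares on amino acid CDR3s, libraries 1 to 3 alone and without the 2 shallow lists were chosen after the data were seen, and the others were planned. Over all alternatives, left-out libraries included, 2102 values of diversity, CDR3 features, overlap and counts kept their direction and their side of the threshold, 183 no longer passed, 46 newly passed, 34 changed sign and 56 moved. Of values of single V and J classes 4996 were kept, 425 no longer passed, 142 newly passed, 26 changed sign and 3 moved. As shares of distinct clones 39 passing values of these classes no longer passed. Counts of differentially abundant (called) CDR3s are given where they moved by over 1.5 times, which they did not under TMM or TMMwsp scaling or with nucleotide CDR3s. For the changes below the cause was not tested. Below, dura and spleen stand for infected minus naive in that tissue, naive and infected for dura minus spleen in such mice, and effect for the dura minus the spleen infection effect. Depth limits these results through truncated lists, of which the naive spleen heavy lists of 5 to 7 clones or about 1000 reads and lambda lists of 20 to 239 reads are the thinnest. Under a minimum count of 10, 2 naive spleen lambda lists gave no value. Pseudocounts were not run, since the values are counts, and isotypes could not be run.

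Without read weights CDR3 hydropathy no longer passed for heavy infected -0.246, kappa dura -0.0241 and lambda naive 0.111. CDR3 hydropathy changed sign for lambda dura 0.0147. CDR3 length newly passed for heavy naive 1.70. CDR3 length no longer passed for kappa spleen 0.0312, naive 0.0434 and effect -0.0524 and lambda effect 0.231. CDR3 length changed sign for lambda dura -0.000358 and infected -0.0259. CDR3 net charge changed sign for kappa dura 0.00810, spleen 0.0238, infected -0.0791 and effect -0.0157 and lambda dura 0.00327. CDR3 net charge no longer passed for kappa naive -0.0634 and lambda infected -0.0217 and effect -0.149. As shares of distinct clones usage changed sign for IGKJ5 dura 2.75, IGHV8 infected 9.63, IGKV14 naive -0.513, infected 0.0804 and effect 0.593 and IGKV16 dura -0.0782. Usage also changed sign for IGHV1-55 spleen 2.8 and effect -3.92, IGHV1-78 dura 1.92, IGKV16-104 dura -0.0782 and IGKV6-15 dura -1.04 and infected -0.611. Usage also changed sign for IGKV6-32 infected 0.641. As shares of distinct amino acid CDR3s usage changed sign for IGKJ5 dura 1.91, IGHV8 infected 10.3, IGKV14 naive -0.476, infected 0.133 and effect 0.609 and IGHV1-55 spleen 2.8 and effect -3.99. Usage also changed sign for IGHV1-78 dura 1.95, IGKV16-104 dura -0.0369, IGKV6-15 dura -0.445 and infected -0.430 and IGKV6-32 infected 0.997. Passing V and J classes moved for dura 20. With the Gini coefficient clonality no longer passed for heavy naive -0.0894 and lambda infected -0.0629. Clonality newly passed for kappa infected -0.0466 and lambda dura -0.0402 and effect -0.253. At a minimum count of 10 clonality no longer passed for kappa naive -0.105 and lambda infected -0.0542. Distinct clones changed sign for heavy spleen 46.2 and naive 59.6 and lambda spleen 2.29 and effect -2.01. Distinct clones newly passed for heavy effect -86.2 and lambda naive 4.08. Top clone share newly passed for heavy spleen -45.4. Top clone share no longer passed for lambda naive -5.46. At a minimum count of 2 clonality newly passed for heavy effect 0.273 and lambda effect -0.196. Distinct clones changed sign for heavy naive 63.2. Distinct clones newly passed for heavy effect -111 and lambda naive 3.01. Top clone share changed sign for lambda spleen -2.64. Top clone share newly passed for lambda effect 6.00. After rarefaction clonality changed sign for lambda naive -0.100. Without rarefaction distinct clones newly passed for lambda naive 26.2. Distinct clones no longer passed for lambda infected 8.33. Distinct clones changed sign for lambda effect -17.8.

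Over ceiling totals top clone share changed sign for heavy dura -14.3, infected -27.4 and effect -5.17 and lambda naive 55.0 and effect -57.0. Top clone share no longer passed for heavy naive -22.2 and lambda infected -2.02. Top clone share newly passed for kappa infected -4.68 and lambda spleen 65.3. The ceiling total is too high for the naive spleen lambda lists, which hold 20 to 239 reads with a lowest count of 1. Lambda values over ceiling totals that involve naive spleen, here and for amino acid sums, are therefore not read as effects of truncation. With the top 100 clones top clone share no longer passed for heavy dura 3.21 and lambda naive 0 and infected 0. Top clone share changed sign for heavy naive 5.59 and effect -4.41. With clones summed to amino acid CDR3s clonality no longer passed for kappa naive -0.0930. Top clone share no longer passed for kappa effect 22.3 and lambda infected -3.10. With these sums over ceiling totals top clone share changed sign for heavy dura -14.5, infected -27.3 and effect -5.39 and lambda naive 57.5 and effect -58.4. Top clone share no longer passed for heavy naive -21.9 and lambda infected -0.888. Top clone share newly passed for kappa infected -4.91 and lambda spleen 65.7. With the top 1 clone top clone share newly passed for heavy spleen -39.1 and lambda dura 3.38. Top clone share no longer passed for kappa naive -8.50 and effect 7.69. Without the 2 shallow naive spleen lists distinct clones changed sign for heavy spleen 77.0 and naive 102. Distinct clones newly passed for heavy effect -158. Clonality newly passed for heavy spleen -0.284 and effect 0.335. Top clone share newly passed for heavy spleen -45.4. CDR3 net charge newly passed for heavy spleen -1.17, naive -0.815 and effect 1.28. Called CDR3s moved for naive 89. With libraries 1 to 3 alone, where 3 libraries per group leave exact tests unable to pass and a value moved if shifted by over 1 SD, distinct clones moved for heavy dura -58.0. Clonality moved for heavy spleen -0.450. Top clone share moved for heavy spleen -62.1. CDR3 net charge moved for heavy infected -0.130. CDR3 hydropathy moved for heavy infected -0.285. Called CDR3s moved for dura 29, naive 71 and infected 32.

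With the Jaccard index overlap between libraries changed sign for heavy spleen 0.0389 and lambda dura 0.0639. Overlap between libraries no longer passed for lambda naive 0.0664. With detection in 2 libraries as the filter called CDR3s moved for dura 103, naive 37 and infected 10. With 10 reads in 6 libraries as the filter called CDR3s moved for dura 60, spleen 6, naive 21 and infected 10. With unlisted CDR3s at the lowest listed count called CDR3s moved for spleen 90 and infected 114. With that and ceiling totals called CDR3s moved for spleen 95 and infected 104. With DESeq2 called CDR3s moved for infected 95. Within 1 substitution of the fixed list, 2 libraries held a CDR3 against 0 by exact match.

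The replicate numbers were not shown to pair the samples. The check used 99 kappa CDR3s listed in many libraries, which may mark a mouse poorly, so it cannot exclude that a number marks a mouse. Deviations of same-numbered libraries correlated between -0.205 and 0.258, over 0.1 in at most 1 of 6 pairs of a comparison, and at most 2 libraries of a comparison correlated best with their own number. With 64 sign flips the smallest exact p is 0.03125, and no adjusted value came below 0.0987, so that permutation calls lost under the block say nothing of weaker effects. The edgeR counts are not limited by sign flips, and the cause of their fall under the block was not tested. With the replicate number as a block distinct clones no longer passed for heavy dura -80.9 and infected -56.1, kappa spleen 63.5, naive 62.7 and effect -59 and lambda infected 2.94. Clonality no longer passed for heavy naive -0.289, kappa spleen -0.111 and naive -0.105 and lambda infected -0.156. Top clone share no longer passed for heavy dura 26.9, naive -39.9 and effect 55.4, kappa spleen -27.6, naive -25.9 and effect 24.2 and lambda naive -7.21 and infected -4.59. CDR3 length no longer passed for heavy dura -3.36, infected -2.49 and effect -4.51, kappa spleen 0.140, naive 0.165 and effect -0.158 and lambda dura 0.204, infected 0.315 and effect 0.306. CDR3 net charge no longer passed for kappa dura -0.0504, spleen -0.255, naive -0.193 and effect 0.204 and lambda dura -0.0512, infected -0.0883 and effect -0.107. CDR3 hydropathy no longer passed for heavy dura -0.414, infected -0.621 and effect -0.610, kappa dura -0.106 and lambda dura -0.0485 and naive 0.160. Passing V and J classes moved for dura 0, spleen 0, naive 0, infected 0 and effect 0. Called CDR3s moved for dura 31, spleen 0 and infected 0. The counts of called CDR3s without the block were 188, 56 and 51, and for naive dura against spleen 134 against 116 with it.

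With each library left out in turn, ranges were as follows where a call, a sign or a count changed, with the libraries whose loss changed it. Heavy CDR3 length (effect) was -5.45 to -3.80 and no longer passed without naive spleen 1 to 3 and infected spleen 3 and 5. Kappa CDR3 length (effect) was -0.201 to -0.140 and no longer passed without naive spleen 1 to 4. Kappa CDR3 length (dura) was -0.0211 to -0.0140 and newly passed without naive dura 3 and 4. Kappa CDR3 length (naive) was 0.147 to 0.208 and no longer passed without naive spleen 1 to 4. Kappa CDR3 length (spleen) was 0.123 to 0.184 and no longer passed without naive spleen 1 to 5 and infected spleen 1 to 6. Lambda CDR3 length (effect) was 0.238 to 0.363 and no longer passed without naive dura 2 to 5 and infected dura 3, 4 and 6 and naive spleen 2, 4, 5 and 6 and infected spleen 1, 3, 4, 5 and 6. Heavy CDR3 net charge (effect) was 0.723 to 1.05 and newly passed without naive spleen 6. Kappa CDR3 net charge (effect) was 0.189 to 0.237 and no longer passed without naive dura 3, 4 and 6 and infected dura 1 and 2 and naive spleen 1, 2, 3, 4 and 6 and infected spleen 1 to 6. Lambda CDR3 net charge (spleen) was 0.0435 to 0.0712 and newly passed without naive spleen 1. Heavy overlap between libraries (infected) was 0.163 to 0.396 and newly passed without infected dura 1 and 3. Heavy overlap between libraries (naive) was 0.153 to 0.373 and no longer passed without naive dura 3 to 6 and naive spleen 4 to 6. Lambda overlap between libraries (infected) was 0.0773 to 0.139 and no longer passed without infected spleen 1 and 2. Lambda overlap between libraries (naive) was 0.139 to 0.406 and no longer passed without naive spleen 2. Heavy share of CDR3s with an inner cysteine (spleen) was 0.162 to 0.765 and newly passed without naive spleen 5. Kappa IGKJ4 (effect) was -3.86 to 5.19 and changed sign without naive spleen 6. Heavy clonality (effect) was 0.229 to 0.338 and newly passed without infected dura 1, 3 and 4 and naive spleen 5 and infected spleen 4. Heavy clonality (naive) was -0.357 to -0.248 and no longer passed without naive dura 1 to 6. Heavy clonality (spleen) was -0.286 to -0.177 and newly passed without naive spleen 5. Kappa clonality (effect) was 0.0454 to 0.115 and newly passed without naive spleen 5. Kappa clonality (naive) was -0.127 to -0.0573 and no longer passed without naive dura 1 to 6 and naive spleen 1, 2, 3, 4 and 6. Lambda clonality (effect) was -0.237 to -0.140 and newly passed without naive spleen 1. Lambda clonality (dura) was -0.0334 to -0.0233 and newly passed without naive dura 3 and infected dura 3. Called CDR3s (dura) was 90 to 175 and moved without infected dura 1 to 6. Called CDR3s (infected) was 8 to 74 and moved without infected dura 1, 2, 4, 5 and 6 and infected spleen 1 and 2. Called CDR3s (naive) was 30 to 120 and moved without naive dura 4 and 6 and naive spleen 1 to 6. Called CDR3s (spleen) was 32 to 57 and moved without naive spleen 2 and 3. Heavy distinct clones (effect) was -147 to -32.9 and newly passed without naive spleen 5. Heavy distinct clones (naive) was -23.3 to 91.2 and changed sign without naive spleen 5. Heavy distinct clones (spleen) was -48.1 to 66.4 and changed sign without naive spleen 5. Passing V and J classes (infected) was 15 to 22 and moved without infected dura 5. Passing V and J classes (spleen) was 8 to 22 and moved without naive spleen 5. Heavy top clone share (dura) was 24 to 32.5 and no longer passed without naive dura 4 to 6. Heavy top clone share (naive) was -52.6 to -36.5 and no longer passed without naive dura 1 to 6 and naive spleen 1, 2, 3, 4 and 6. Heavy top clone share (spleen) was -41.2 to -22.5 and newly passed without naive spleen 5. Kappa top clone share (effect) was 19.5 to 28.4 and no longer passed without naive dura 3 to 6 and infected dura 1 and 2 and naive spleen 1, 2, 3, 4 and 6 and infected spleen 1 to 6. Lambda top clone share (dura) was 2.43 to 4.37 and newly passed without naive dura 1.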

Other observations

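The D gene shares and near-copy shares in this part were computed after the other results had been seen, and none was tested.

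D genes form the middle of the heavy chain CDR3, and their mean shares were taken for each group. IGHD2-2, the D gene called for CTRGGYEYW, held 29.4% ± 20.2 of heavy chain reads in infected dura (SD, n = 6) and 1.86% ± 1.56 in naive dura, 0.798% ± 1.60 in naive spleen and 2.48% ± 3.10 in infected spleen. IGHD3-1 was at 9.11% ± 3.70 in infected dura and at 1.10% ± 0.784, 0.361% ± 0.611 and 1.61% ± 1.00 in naive dura, naive spleen and infected spleen. IGHD1-1 was at 36.4% ± 9.82 in naive and 12.0% ± 4.5 in infected dura, and at 12.6% ± 9.14 in naive and 25.6% ± 12.2 in infected spleen. IGHD2-5 was at 10.4% ± 3.93 in naive dura and between 0.975% and 2.77% in the other groups. No D gene was called for 19.0% ± 2.61 of reads in naive dura, 25.4% ± 14.3 in infected dura, 51.0% ± 41.2 in naive spleen and 37.1% ± 22.3 in infected spleen.

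Some heavy chain CDR3s had another CDR3 of the same library and V gene at 1 amino acid substitution. They made up 10.8% ± 2.70 of distinct CDR3s in naive dura and 0.926% ± 2.27 in infected dura (SD, n = 6), the latter from library 3 alone at 5.56%. Naive dura lists held 91 to 135 distinct heavy CDR3s and infected dura lists 17 to 36, and a longer list gives more chances of a near-copy. Infected spleen had 0% in all 6 libraries, and naive spleen 14.4% ± 20.7, with 50%, 28.6% and 7.54% in libraries 1, 2 and 5 and 0% in the others, from lists as short as 5 clones.

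Among kappa CDR3s listed in nearly all libraries, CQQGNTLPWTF (IGKV10-96) held 1.67% ± 0.231 in naive dura, 1.36% ± 0.230 in infected dura, 1.74% ± 1.54 in naive spleen and 1.43% ± 0.277 in infected spleen (SD, n = 6). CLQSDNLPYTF (IGKV17-121) was at 0.50% ± 0.0842, 1.26% ± 0.147, 0.654% ± 0.460 and 1.06% ± 0.399 in the same order. The lambda CDR3 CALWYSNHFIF (IGLV1, IGLJ3), listed in 22 libraries, was at 7.07% ± 1.66, 10% ± 3.62, 3.02% ± 4.69 and 11.6% ± 7.91. The heavy CDR3 listed in the most libraries, CARGAYW (IGHV1-80, IGHJ3), was in 9, 6 of them naive dura and 3 naive spleen, with 5 nucleotide sequences.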
